A study of Mus musculus with 12 samples.

How the data were processed

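Whole-lung total RNA from 12 samples had been labelled as biotinylated cRNA and hybridized to Affymetrix expression arrays, 1 array per sample. The deposited table holds 1 log2 value for each of 45101 probe sets on each array, as an RMA summary made by the authors (background correction, quantile normalization and a fit over probes). The submitters' processing notes name affy, RMA and limma without versions or settings. Detection calls were not used here, so signal near background was judged from the level alone. The labels name no genome build. The labels do not state whether the 3 replicates of a group are separate animals. For arrays, their number (3 per group) limits the precision.

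Of the probe sets, 34958 are paired with 1 gene in the annotation, 932 with several and 9211 with none. Those with 1 gene were used, and 34754 of them matched a mouse gene table by Entrez identifier. For each of 18194 genes the probe set with the highest mean over the 12 arrays was tested; 9012 genes have more than 1. No filter on dim probe sets and no minimum fold was applied. Gene order and neighbours of Retnlb came from the GRCm38.p6 gene table and were used for names and distances only.

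All 12 arrays entered 1 limma fit (limma 3.58.1, statmod 1.5.0, R 4.3.3) with a mean per group, without a block, followed by eBayes without trend (8 residual and 4.86 prior degrees of freedom). The 7 contrasts were bleomycin against saline in each genotype, the difference between these responses, knockout against wild type after each treatment, and the averages over genotypes and over treatments. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The SE of a change is from this fit, and the SD of a group is over its 3 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

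Before the data were examined, 42 lists of genes (786 names, 722 measured) were fixed for matrix, immune, epithelial, endothelial and stromal genes, for pathways, and for tissues that a lung sample can hold beside lung. Members paired with no probe set alone were not analysed here. Each list was tested with limma's camera, preset correlation 0.01, with Benjamini-Hochberg over the lists. The alternatives were a correlation estimated per list and fry. Counts adjusted over the list alone take Benjamini-Hochberg over its members.

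The genes named in the text follow a rule fixed at the same time. Among called genes whose arrays do not overlap between the groups, which chance gives in 10% of genes with 3 arrays against 3, the 10 largest rises and 10 largest falls were taken for bleomycin in wild type and 5 of each for the other contrasts. The condition on overlap was dropped for the difference between responses. Genes named only by a clone or model and immunoglobulin or T cell receptor segments were left out. Retnlb and its family were always given. From each list described, up to 4 members with the smallest p were taken, and textbook markers that did not pass.

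The size of the response was compared over genes called in the average over genotypes, as a ratio of medians and as a score per array with an exact permutation test, two-sided. Genes within 10 Mb of Retnlb were counted among genes called for genotype on average and tested with Fisher's exact test, two-sided. Alternatives tried were a filter on genes with a mean under 5, array medians subtracted, a repeated quantile normalization, eBayes with trend and robust, the mean of all probe sets of a gene, all probe sets, only the groups of a contrast, array weights, a 2-fold minimum, the replicate number as a block, the 200 genes with the smallest p for the size of the response, other windows, and each array left out in turn.

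Control probe sets for 18S ribosomal RNA, and the 3 prime minus 5 prime signal of actin and Gapdh, were compared between groups as signs of RNA quality. The knockout response was tested against the wild type response times a common multiplier, gene by gene and, after the result was seen, list by list. Also after the result was seen, the named falls were correlated with the mean of the other cardiac and adipocyte genes as deviations from group means over the 12 arrays, with an exact permutation of arrays within groups and Benjamini-Hochberg over all these tests. The procedure was tested on simulated data with 18194 genes and 50 genes changed at each size. For bleomycin in wild type, 60% of changes of 0.5 on the log2 scale were called, 94% of changes of 1 and 98% of changes of 2. For the difference between responses these were 18%, 66% and 98%. In wild type, 6.38% of calls were false, and in the comparison simulated without a change 0 genes were called.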

Results

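Whole-lung RNA of C57BL/6 mice was measured on 12 Affymetrix expression arrays, 3 in each of 4 groups. The groups were wild type and FIZZ2 knockout lungs taken 21 days after an endotracheal injection of saline or of bleomycin. Bleomycin is a DNA-breaking antitumour drug that injures the lung and is used in mice to produce scarring. FIZZ2 is RELM-beta, a secreted protein of the resistin family that is encoded by Retnlb. The median log2 value of an array lay between 5.58 and 5.68, and the correlation across probe sets between arrays of the same group lay between 0.988 and 0.997 (12 pairs; probe sets are not independent replicates). The labels do not state that the replicates are separate animals, so the p-values measure the spread between these samples, and 3 arrays per group limit the precision.

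Retnlb, the targeted gene, was dim in every group, so its level offers no check of the genotype labels. Its log2 difference between knockout and wild type bleomycin lungs was -0.347 and did not pass (limma, adjusted p = 0.0502). Wild type bleomycin arrays (3.80 to 4.13) lay above knockout bleomycin arrays (3.49 to 3.72). Chance gives such a separation, in either direction, in 10% of genes. Its mean log2 value was 3.69 ± 0.14 (SD, n = 3) in wild type saline lungs, 3.97 ± 0.17 in wild type bleomycin lungs, 3.69 ± 0.14 in knockout saline lungs and 3.63 ± 0.12 in knockout bleomycin lungs, between percentiles 17.0 and 31.1 of the probe sets of an array. Retnla, the related FIZZ1 gene of alternatively activated macrophages, rose 4.02-fold with bleomycin in wild type lungs (log2 change 2.01 ± 0.22, SE, n = 3 per group, adjusted p = 3.13e-05). In knockout lungs the log2 change of Retnla was -0.32 ± 0.22 (adjusted p = 0.507), with a sign that turned without knockout bleomycin replicate 1 (0.012), and the responses of the 2 genotypes differed by -2.33 ± 0.32 (adjusted p = 0.00298). Retnla lies directly beside Retnlb in the order of measured genes. An effect of the targeted allele on this neighbour was not separated from a changed response. Retn, which encodes resistin, passed the test in none of the 5 comparisons between pairs of groups or responses (log2 change -0.97 in wild type and -1.16 in knockout lungs with bleomycin, adjusted p = 0.155 and 0.218). Retnlg has no probe set paired with it alone and was not analysed here.

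**Figure D1:**
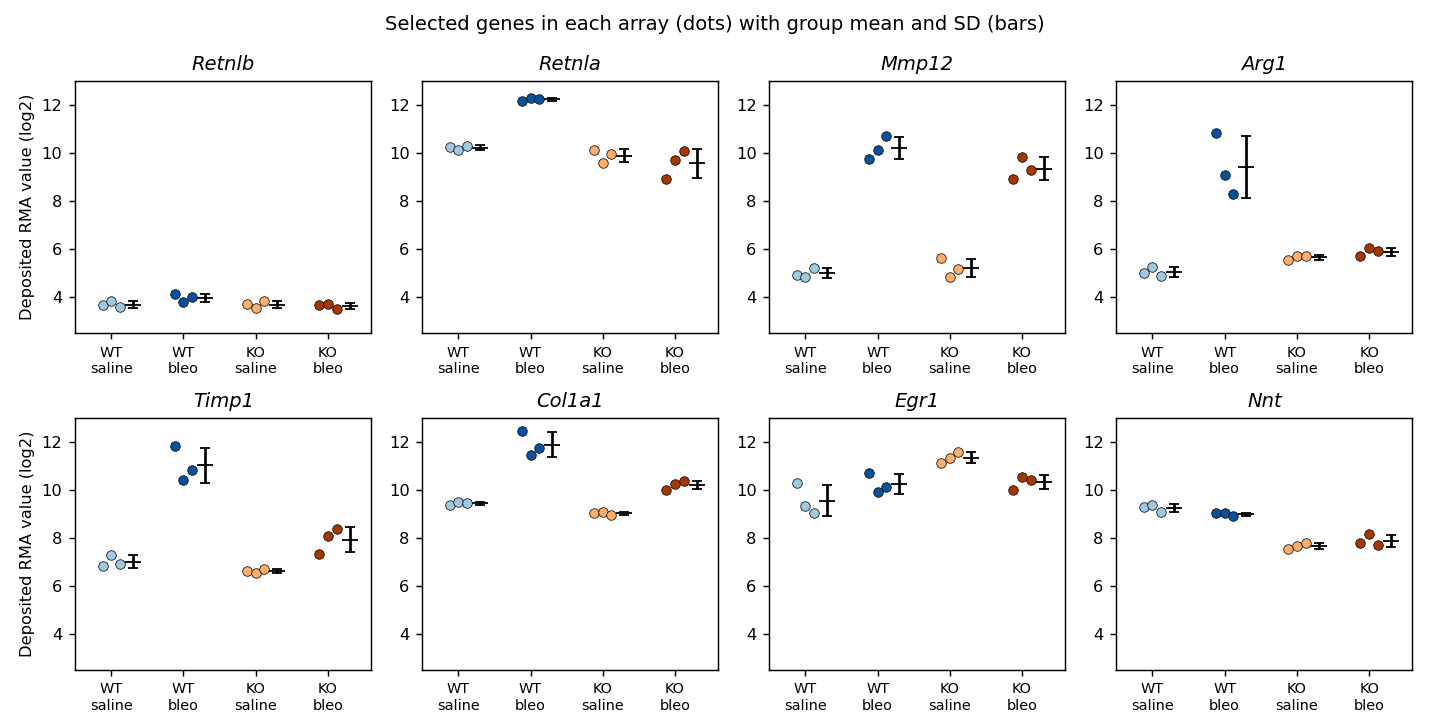
Log2 values of 8 genes on each of the 12 arrays (points), with the mean and SD of each group of 3 (bars). Retnlb stays between 3.494 and 4.135 on every array, whereas Arg1 has a mean of 9.42 in wild type bleomycin lungs and of 5.88 in knockout bleomycin lungs.

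What bleomycin changed in wild type lung was read from the 3 wild type bleomycin arrays against the 3 wild type saline arrays. Mmp12, the macrophage metalloelastase, rose 36.9-fold (log2 change 5.21 ± 0.26, SE, n = 3 per group, adjusted p = 1.58e-07). The acute-phase gene Saa3 rose 31.4-fold (4.97 ± 0.50, adjusted p = 1.44e-05), and Arg1, an arginase of alternatively activated macrophages, rose 20.8-fold (4.38 ± 0.43, adjusted p = 1.38e-05). Other large rises were those of the adhesion molecule Chl1 (at least 21-fold), the matrix proteins Tnc (16.5-fold) and Thbs4 (10.7-fold), the protease inhibitor Timp1 (16.1-fold), the chemokine Ccl8 (11.3-fold), the neutrophil antigen Cd177 (11-fold) and the spindle gene Psrc1 (10.6-fold). Chl1 lay between 3.593 and 3.676 in wild type saline lungs, as dim as Retnlb, so its change is a lower bound. The largest falls were those of Fabp1, a fatty acid binding protein (log2 change -3.17 ± 0.30, to a mean of 3.96, near background, so a lower bound), Ankrd63 (-3.03), Bex2 (-2.99), the amino acid transporter Slc7a10 (-2.91) and Hamp, which encodes the iron hormone hepcidin (-2.83). Nppa, Smpx, Nrn1, Acoxl and Ckmt2 fell by log2 changes of -2.73 to -2.62. The call of Nppa was lost without wild type saline replicate 1 (adjusted p = 0.0616) or 3 (0.109) and without wild type bleomycin replicate 1 (0.0783) or 2 (0.118), and with trend and robust eBayes (0.0964). In a test chosen after the result was seen, deviations from the group means over the 12 arrays followed those of the cardiac muscle genes for Smpx (r = 0.992, exact permutation test, adjusted p = 0.0463), Ckmt2 (0.963, adjusted p = 0.0463) and Nppa, itself such a gene (0.921, adjusted p = 0.0463). Hamp had r = 0.879 (adjusted p = 0.15). For these 4 genes, a change in lung was not separated from a change in the amount of heart or pulmonary vein tissue. In total 5045 of 18194 genes passed, 2428 higher and 2617 lower, and 738 of them changed at least 2-fold. For bleomycin in wild type, 2805 passed without wild type saline replicates 2 and 3.

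Lists of extracellular matrix genes were called higher in wild type lungs, that of contractile genes not. Of 23 measured collagen chains, 20 rose, 1 fell and 2 did not pass (20 and 1 adjusted over the list alone), with Col1a1 up 5.45-fold (log2 change 2.45 ± 0.19, adjusted p = 2.61e-06), Col5a2 up 5.29-fold and Col3a1 up 2.12-fold. The collagen list had camera's adjusted p = 9.41e-15, and adjusted p = 0.154 with an estimated correlation. Of 33 matrix glycoproteins and proteoglycans, 26 rose and 2 fell (27 and 2 adjusted over the list alone), among them elastin (Eln, 9.89-fold) and fibronectin (Fn1, 4.37-fold). For the matrix glycoproteins and proteoglycans, camera gave adjusted p = 5.89e-15, and adjusted p = 0.104 with an estimated correlation. Of 26 matrix proteases and their inhibitors, 20 rose and 1 fell (20 and 1 adjusted over the list alone), with the cathepsins Ctsk (4.97-fold) and Ctss (2.71-fold) beside Mmp12 and Timp1. For the matrix proteases and their inhibitors, camera gave adjusted p = 2.69e-13, and adjusted p = 0.104 with an estimated correlation. Of 17 genes of collagen processing and crosslinking, 11 rose and 1 fell (11 and 2 adjusted over the list alone). Lox, a crosslinking enzyme, rose 4.66-fold and Pcolce2, an enhancer of procollagen cleavage, fell by 1.91 on the log2 scale; the list had adjusted p = 1.59e-05, and adjusted p = 0.185 with an estimated correlation. Of 24 TGF-beta and growth factor genes, 15 rose and 2 fell (15 and 3 adjusted over the list alone), with Igf1 up 6.32-fold and the activin antagonist Fst up 6.45-fold. For the TGF-beta and growth factor genes, camera gave adjusted p = 3.01e-07, and adjusted p = 0.102 with an estimated correlation. Of 14 contractile genes of myofibroblasts and smooth muscle, 2 rose (Tpm1 and Cald1, also 2 adjusted over the list alone), and Acta2 had a log2 change of 0.30 ± 0.19 (adjusted p = 0.259); the list had adjusted p = 0.157, and adjusted p = 0.789 with an estimated correlation. Tpm1 rose 1.60-fold on its brightest probe set and did not pass as the mean of all its probe sets (log2 change 0.30, adjusted p = 0.0898).

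The lists of macrophage markers and cell cycle genes were called higher, and those of NK and T cell markers lower, in the same comparison. Of 27 macrophage and monocyte markers, 21 rose and 1 fell (21 and 1 adjusted over the list alone), with Gpnmb up 7.14-fold (log2 change 2.84 ± 0.13, adjusted p = 9.41e-08) and Cd68 up 4.48-fold. For the macrophage and monocyte markers, camera gave adjusted p = 3.53e-15, and adjusted p = 0.104 with an estimated correlation. All 27 cell cycle genes rose (27 adjusted over the list alone), with the mitotic kinase Cdk1 up 6.44-fold. For the cell cycle genes, camera gave adjusted p = 1.56e-26, and adjusted p = 0.104 with an estimated correlation. Of 29 genes of type 2 cytokines and alternative macrophage activation, 10 rose and 2 fell (11 and 3 adjusted over the list alone), with the scavenger receptor Msr1 up 7.55-fold. For the genes of type 2 cytokines and alternative macrophage activation, camera gave adjusted p = 0.00139, and adjusted p = 0.154 with an estimated correlation. Of 26 chemokines, 14 rose and 3 fell (16 and 3 adjusted over the list alone), with Ccl9 up 6.30-fold. For the chemokines, camera gave adjusted p = 9.33e-07, and adjusted p = 0.154 with an estimated correlation. Of 15 complement genes, 11 rose (12 adjusted over the list alone), with the receptor C3ar1 up 7.09-fold and C1qa up 5.62-fold. For the complement genes, camera gave adjusted p = 3.01e-07, and adjusted p = 0.154 with an estimated correlation. Of 14 markers of NK and cytotoxic cells, 12 fell and 1 rose (12 and 1 adjusted over the list alone), with the granzyme Gzma at a log2 change of -2.29 ± 0.23 and Nkg7 at -1.59. For the markers of NK and cytotoxic cells, camera gave adjusted p = 7.72e-07, and adjusted p = 0.154 with an estimated correlation. Of 18 T cell markers, 10 fell and 2 rose (10 and 2 adjusted over the list alone), with Cd8b1 at -1.46. For the T cell markers, camera gave adjusted p = 0.0262, and adjusted p = 0.324 with an estimated correlation; the call was lost without wild type bleomycin replicate 2 (adjusted p = 0.0662). Of 17 B and plasma cell markers, 8 fell and 2 rose (10 and 2 adjusted over the list alone): the B cell receptor gene Cd79b fell by 1.19 on the log2 scale, whereas Jchain and Igha, which plasma cells express, rose by 1.47 and 0.96. The list had adjusted p = 0.0575, and adjusted p = 0.630 with an estimated correlation.

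The lists of ciliated cell, club cell and vascular markers were called lower, and that of injury-associated keratin genes higher. Of 19 ciliated cell markers, 16 fell and 3 did not pass (16 fell and 1 rose adjusted over the list alone), with Tppp3 at a log2 change of -1.36 ± 0.13. For the ciliated cell markers, camera gave adjusted p = 9.9e-08, and adjusted p = 0.231 with an estimated correlation. Of 15 club cell markers, 9 fell and 1 rose (10 and 1 adjusted over the list alone), with Cyp4b1 at -1.64 ± 0.17. For the club cell markers, camera gave adjusted p = 0.000211, and adjusted p = 0.324 with an estimated correlation. Of 24 vascular endothelial markers, 15 fell (17 fell and 1 rose adjusted over the list alone), with the VEGF receptor Kdr at -0.88 and Bmp6 at -1.36. For the vascular endothelial markers, camera gave adjusted p = 7.72e-07, and adjusted p = 0.286 with an estimated correlation. Of 18 injury-associated and basal keratin genes, 10 rose (11 adjusted over the list alone), with Sfn up 3.44-fold and Cldn4 up 3.47-fold. For the injury-associated and basal keratin genes, camera gave adjusted p = 6.21e-07, and adjusted p = 0.154 with an estimated correlation. Of 17 alveolar type 2 markers, 5 fell, among them the surfactant gene Sftpa1 at -0.72 (6 fell and 1 rose adjusted over the list alone), and of 17 alveolar type 1 markers, 2 rose and 3 fell, also adjusted over the list alone; these lists had adjusted p = 0.0996 and 0.413. All 12 cardiac muscle genes, markers of heart or pulmonary vein tissue, fell (12 adjusted over the list alone), with Myh6 at -2.12 ± 0.44 and Myl7 at -2.18, at adjusted p = 7.75e-06, and adjusted p = 0.324 with an estimated correlation. Camera called 22 of the 42 lists, 15 up and 7 down, and 0 of 42 with an estimated correlation; fry, which tests whether the genes of a list move on balance in 1 direction, called 24.

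The response of knockout lungs was read from the 3 knockout bleomycin arrays against the 3 knockout saline arrays. Mmp12 rose 17.6-fold (log2 change 4.14 ± 0.26, SE, n = 3 per group, adjusted p = 7.48e-06), the plasma cell gene Jchain 7.19-fold (2.85 ± 0.29, adjusted p = 0.000358), Gpnmb 4.85-fold (2.28 ± 0.13, adjusted p = 4.35e-06), Psrc1 4.44-fold and the macrophage receptor Trem2 4.17-fold. The largest falls were those of the stefin gene Stfa2l1 (log2 change -1.97 ± 0.27, to a mean of 4.16, near background, so a lower bound), Ankrd63 (-1.70), Slfn4 (-1.62), the mitochondrial gene Cox8b (-1.55) and the neutrophil gene S100a9 (-1.53). Stfa2l1 and S100a9 were also higher in knockout than in wild type saline lungs (log2 difference 1.86 and 1.37, adjusted p = 0.00895 and 0.0325). The call of Cox8b was lost without knockout saline replicate 1 (adjusted p = 0.0682) or knockout bleomycin replicate 2 (0.0822). Over the arrays, Cox8b followed the adipocyte genes in the test described above (r = 0.854, exact permutation test, adjusted p = 0.0463), so that fat near the lung was not separated from lung. Arg1, Saa3 and Chl1 had log2 changes of 0.23, 1.03 and 0.51 and did not pass (adjusted p = 0.841, 0.297 and 0.264). In total 594 genes passed, 360 higher (60.6%) and 234 lower, 90 of them at least 2-fold; with array medians subtracted, 75.5% of the called genes were higher. The count was 246, 211 or 292 without knockout saline replicate 1, 2 or 3, and 245 or 292 without knockout bleomycin replicate 2 or 3; for bleomycin in knockout, array weights gave 1286.

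The lists of collagen chains, macrophage markers and cell cycle genes were called higher in knockout lungs too, with fewer members passing than not. Of 23 collagen chains, 9 rose (10 adjusted over the list alone), with Col3a1 up 2.20-fold (log2 change 1.14 ± 0.10, adjusted p = 0.000147) and Col5a2 up 2.65-fold. For the collagen chains, camera gave adjusted p = 1.07e-09, and adjusted p = 0.225 with an estimated correlation. Of 27 macrophage and monocyte markers, 13 rose (17 adjusted over the list alone), with Cd68 up 2.20-fold. For the macrophage and monocyte markers, camera gave adjusted p = 7.86e-16, and adjusted p = 0.225 with an estimated correlation. Of 27 cell cycle genes, 12 rose (17 adjusted over the list alone), with Cdk1 up 2.68-fold. For the cell cycle genes, camera gave adjusted p = 4.41e-13, and adjusted p = 0.225 with an estimated correlation. Of 26 matrix proteases and inhibitors, 9 rose and 1 fell (11 and 1 adjusted over the list alone), with Mmp2 up 2.93-fold. For the matrix proteases and inhibitors, camera gave adjusted p = 3.62e-07, and adjusted p = 0.225 with an estimated correlation. Among the 17 B and plasma cell markers, 4 rose (4 adjusted over the list alone), with Igha up 4.35-fold (2.12 ± 0.16, adjusted p = 4.89e-05). That list had a median of -0.11 and a mean of 0.31, adjusted p = 0.287, and adjusted p = 0.755 with an estimated correlation. Of 14 contractile genes, 4 fell and 0 rose (6 and 0 adjusted over the list alone), with a median of -0.51 against 0.16 in wild type lungs. Lmod1 had -0.65, a call lost without knockout bleomycin replicate 2 (adjusted p = 0.0535) or 3 (0.0638), and Acta2 had -0.62 (adjusted p = 0.0949). Contractile genes as a list had adjusted p = 1.52e-06, and adjusted p = 0.245 with an estimated correlation. Among lists of tissues beside lung, of 12 cardiac muscle genes 3 fell (11 adjusted over the list alone), with a median of -1.22, at adjusted p = 1.38e-08, and adjusted p = 0.225 with an estimated correlation. Of 10 adipocyte genes 0 passed (8 lower adjusted over the list alone), with a median of -1.48, at adjusted p = 4.28e-05, and adjusted p = 0.225 with an estimated correlation. Skeletal muscle (0 of 12 passing, 0 adjusted over the list alone) and thymocyte lists (1 of 10 lower, 2 adjusted over the list alone) were not called (adjusted p = 0.689 and 0.0963). Camera called 23 lists, 12 up and 11 down, and 0 with an estimated correlation, and fry called 12.

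Genes called in 1 genotype overlapped with those called in the other. Of the 360 genes that rose in knockout lungs, 314 also rose in wild type lungs, where independent calls would share 48.0, and of the 234 that fell, 156 also fell, where 33.7 would be shared. In 1 case a gene rose in wild type and fell in knockout lungs. Across all genes, which are not independent replicates, the responses of the 2 genotypes correlated with r = 0.630.

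Whether the knockout altered the response was tested as the difference between the 2 responses. The response of Arg1 was lower in knockout lungs by a log2 difference of -4.15 ± 0.61 (SE, n = 3 per group, adjusted p = 0.00441), that of Saa3 by -3.94 ± 0.70 (adjusted p = 0.00884), and that of Chl1 by -3.88 ± 0.33 (adjusted p = 0.000152), where Chl1 was near background in all groups but wild type bleomycin (means of 3.64, 3.79 and 4.30). Fst (-2.95), the phospholipase Pla1a (-2.93) and Timp1 (-2.69, adjusted p = 0.0066) followed. In the other direction, the response was higher for Acoxl (2.53 ± 0.42, adjusted p = 0.00692), Fabp1 (2.45, near background in wild type bleomycin lungs), Slc7a10 (2.26) and Nrn1 (2.002), genes that fell in wild type lungs. Col1a1 had a difference of -1.27 ± 0.27 (adjusted p = 0.0205). Mmp12, with -1.07 ± 0.37 (adjusted p = 0.115), and Col3a1, with 0.05 ± 0.14 (adjusted p = 0.867), did not pass. In total 914 genes passed, 369 higher (40.4%) and 545 lower, 307 of them at least 2-fold; 50.7% were higher with array medians subtracted and 51.2% after a repeated quantile normalization. The count was 501 without wild type saline replicate 1, 380, 455 or 512 without knockout saline replicate 1, 2 or 3, and 400 without knockout bleomycin replicate 1. For the difference of the bleomycin response between genotypes, array weights gave 1888, the replicate number as a block 601, and leaving out wild type saline replicates 2 and 3 together 151. The 5 prime probe set for 18S ribosomal RNA had a difference of 3.51 (adjusted p = 0.331).

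The lists of cell cycle and matrix genes had a lower response in knockout lungs by camera's preset correlation, and none was called with an estimated correlation. Of 27 cell cycle genes, 20 had a lower and 0 a higher response (26 and 0 adjusted over the list alone), with the mitotic kinases Plk1 at -1.47 ± 0.18 and Aurka at -1.05. For the cell cycle genes, camera gave adjusted p = 2.08e-26, and adjusted p = 0.188 with an estimated correlation. Of 33 matrix glycoproteins and proteoglycans, 12 had a lower and 2 a higher response (20 and 3 adjusted over the list alone), with Fn1 at -1.35 and Thbs4 at -2.65. For the matrix glycoproteins and proteoglycans, camera gave adjusted p = 5.29e-12, and adjusted p = 0.188 with an estimated correlation. Of 26 matrix proteases and inhibitors, 10 had a lower response (14 adjusted over the list alone), with Mmp8 at -1.54. For the matrix proteases and inhibitors, camera gave adjusted p = 4.91e-10, and adjusted p = 0.188 with an estimated correlation. Of 23 collagen chains, 7 had a lower response (13 adjusted over the list alone), with Col8a1 at -2.36, which lies within 10 Mb of Retnlb. For the collagen chains, camera gave adjusted p = 7.03e-09, and adjusted p = 0.279 with an estimated correlation. Of 19 ciliated cell markers, 4 had a higher response (13 adjusted over the list alone), with Tppp3 at 1.12. For the ciliated cell markers, camera gave adjusted p = 5.81e-07, and adjusted p = 0.279 with an estimated correlation. Of 14 NK and cytotoxic markers, 2 had a higher response, Gzma at 1.73 and Nkg7 at 1.15 (8 higher and 1 lower adjusted over the list alone). For the NK and cytotoxic markers, camera gave adjusted p = 0.000174, and adjusted p = 0.279 with an estimated correlation. Camera called 23 lists, 7 up and 16 down, and 0 with an estimated correlation, and fry called 14.

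**Figure D2:**
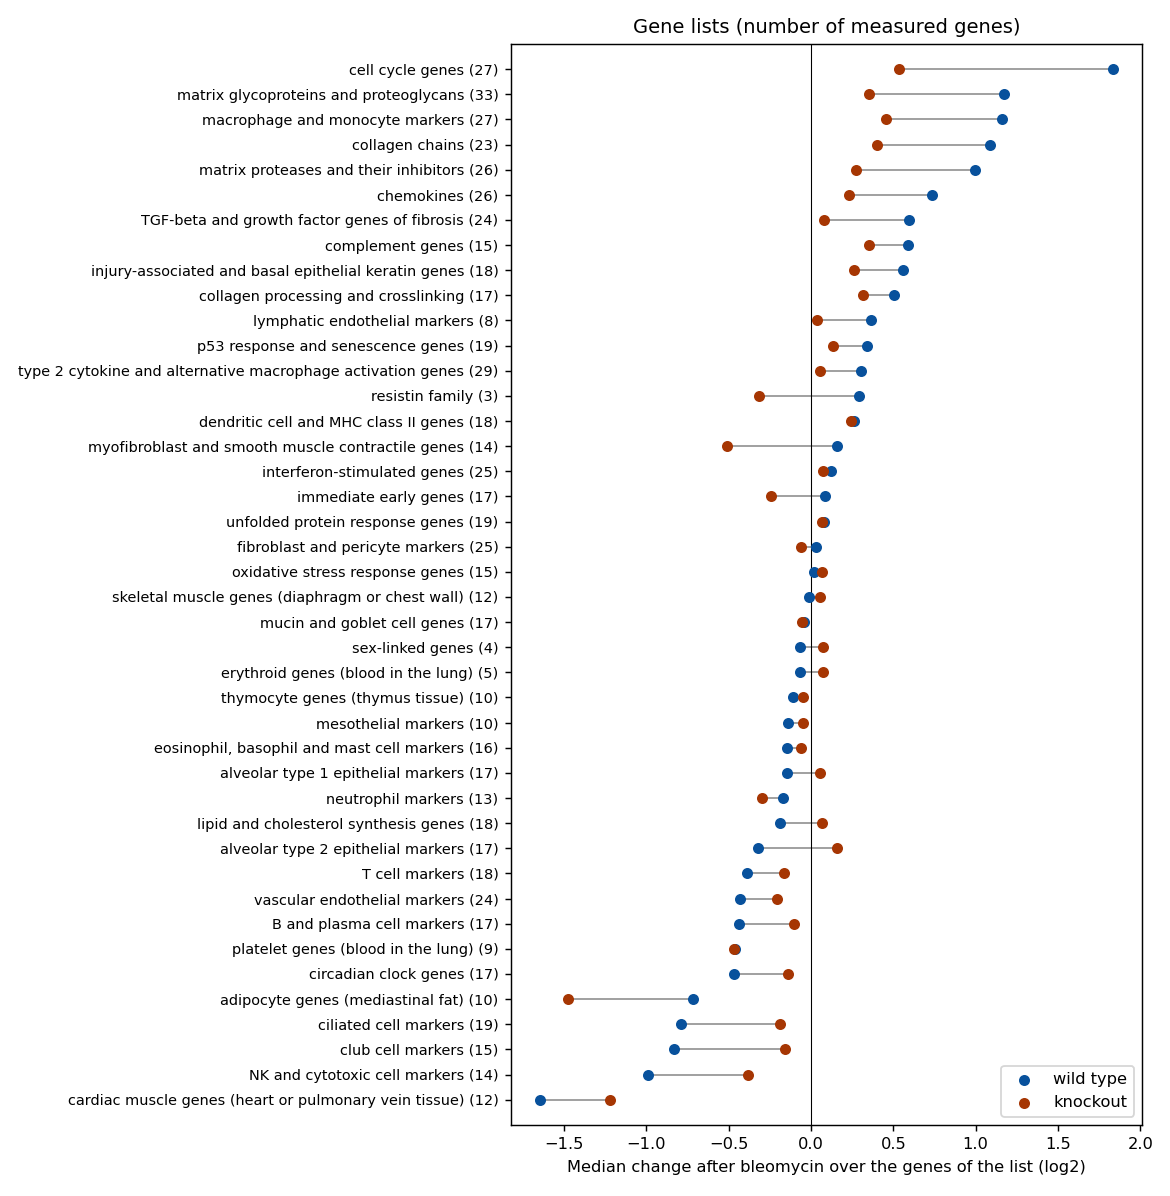
Median log2 change with bleomycin (x axis) over the measured genes of each of the 42 lists (y axis, number of genes in brackets), with 1 point for wild type and 1 for knockout lungs. The cell cycle list has medians of 1.84 in wild type and 0.54 in knockout lungs, and the collagen list of 1.09 and 0.40.

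The size of the response as a whole was compared over the genes called for bleomycin averaged over genotypes. For the 2444 raised genes the median log2 change was 0.51 in wild type and 0.23 in knockout lungs, a ratio of 0.445, and for the 2490 lowered genes it was -0.46 and -0.22, a ratio of 0.481. Of these 4934 genes, 4233 (85.8%) changed less in knockout lungs. The mean of the raised minus the lowered genes, relative to saline lungs of the same genotype, was 1.27 ± 0.15 (SD, n = 3, 1.15 to 1.44) on wild type and 0.57 ± 0.12 (0.43 to 0.66) on knockout arrays, a ratio of 0.449. The SD of the knockout scores divided by the wild type mean was 0.0951, which leaves out the spread of wild type and saline arrays. The exact permutation test gave a two-sided p = 0.1, the smallest p that 3 arrays against 3 can give. Among the genes that changed most on average were Mmp12 (25.5-fold), Tnc (8.10-fold), Psrc1 (6.86-fold), the lectin Clec4n (6.36-fold) and Timp1 (6.34-fold), and, among those lowered, Ankrd63 (log2 change -2.37), Bex2 (-2.04), Slc7a10 (-1.78), the asialoglycoprotein receptor gene Asgr1 (-1.77, near background in wild type bleomycin lungs) and Cox8b (-1.76).

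**Figure D3:**
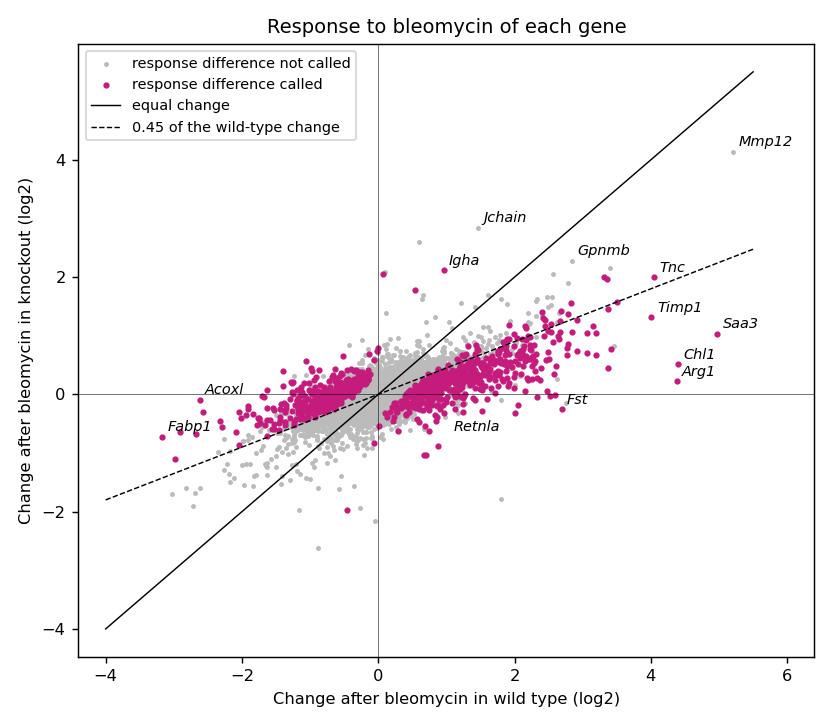
Log2 change with bleomycin of each gene in knockout lungs against that in wild type lungs, with lines for equal responses and for a ratio of 0.45. Arg1 and Saa3 lie at 4.38 and 4.97 on the wild type axis and at 0.23 and 1.03 on the knockout axis.

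How the genotypes differed without bleomycin was read from the 3 knockout against the 3 wild type saline arrays. Mid1, a ubiquitin ligase gene, was 7.52-fold higher in knockout lungs (log2 difference 2.91 ± 0.30, SE, n = 3 per group, adjusted p = 0.000761). This rests on its brightest probe set. Its other probe sets, dim at means of 3.36 and 3.47, had -0.086 and 0.077 (limma over all probe sets, adjusted p = 0.848 and 0.853). After bleomycin they had 0.013 and 0.191 and did not pass either. Lower in knockout lungs were the noncoding RNA gene Dubr (-1.80 ± 0.11, adjusted p = 5.28e-06), Wdfy1 (-1.73 ± 0.14, adjusted p = 6.67e-05), Nnt, the mitochondrial transhydrogenase (-1.59 ± 0.12, adjusted p = 4.17e-05), Slc35a5 (-1.49 ± 0.11, adjusted p = 2.62e-05) and Plcxd2 (-1.42 ± 0.18, adjusted p = 0.00288). In limma over all probe sets, a further one of Slc35a5 (-1.02, adjusted p = 0.12) and one of Plcxd2 (-0.69, adjusted p = 0.13) did not pass. Another of Slc35a5 (-0.68, adjusted p = 0.00667) and further ones of Wdfy1 (-2.016 and -1.995) and Nnt (-1.29) passed. The remaining probe sets of these genes did not. Nnt is a gene of which C57BL/6 substrains carry different alleles. The labels name no substrain of either genotype, so for Mid1, Wdfy1 and the other genes here a difference of background was not separated from the targeted allele. In total 89 genes passed, 54 higher (60.7%) and 35 lower, 24 of them at least 2-fold; with array medians subtracted, 48.1% of the called genes were higher. The count was 56, 50 or 58 without wild type saline replicate 1, 2 or 3, and 41, 37 or 24 without knockout saline replicate 1, 2 or 3. For knockout against wild type after saline, array weights gave 1105 genes, a fit of only these groups 37, and leaving out wild type saline replicates 2 and 3 together 35.

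The lists of immediate early genes and neutrophil markers were called higher in knockout saline lungs, the neutrophil list not with an estimated correlation. Of 17 immediate early genes, which cells switch on within minutes of a stimulus, 6 were higher and 0 lower (11 and 0 adjusted over the list alone), with Egr1 3.5-fold higher (log2 difference 1.81 ± 0.28, adjusted p = 0.0128) and Btg2 1.67-fold higher (0.74 ± 0.11, adjusted p = 0.00895). The list had adjusted p = 1.09e-17, and adjusted p = 0.045 with an estimated correlation. Of 13 neutrophil markers, 5 were higher (5 adjusted over the list alone), with the cytokine Il1b 2.90-fold (1.54 ± 0.23, adjusted p = 0.0111), the calgranulin S100a8 2.39-fold (adjusted p = 0.0153) and the receptor Csf3r 1.90-fold higher (adjusted p = 0.0128). For the neutrophil markers, camera gave adjusted p = 6.45e-09, and adjusted p = 0.219 with an estimated correlation. Erythroid genes, which mark blood left in the lung, had a median of 0.05 with 0 of 5 passing (0 adjusted over the list alone), at adjusted p = 0.758, and adjusted p = 0.943 with an estimated correlation. Platelet genes, which also mark blood, had a median of 0.41 with 0 of 9 passing (2 higher adjusted over the list alone), at adjusted p = 0.000191, and adjusted p = 0.548 with an estimated correlation. B and plasma cell markers had a median of 0.35 with 0 of 17 passing (0 adjusted over the list alone), at adjusted p = 2.93e-05, and adjusted p = 0.548 with an estimated correlation. Of 17 circadian clock genes, which follow the time of day, 2 were lower (6 lower and 1 higher adjusted over the list alone), Cry1 (-0.62) and Ciart (-0.68), and Arntl had 0.63 (adjusted p = 0.079). That list had adjusted p = 0.0111, and adjusted p = 0.436 with an estimated correlation, and was not called without wild type saline replicate 1 (0.121) or as the mean of all probe sets (0.0834). Cry1 lost its call without knockout saline replicate 2 (0.0549), and Ciart without wild type saline replicate 1 (0.164) or 2 (0.143) or knockout saline replicate 1 (0.0898), 2 (0.182) or 3 (0.116) and with the replicate number as a block (0.096). Egr1 lost its call without wild type saline replicate 2 (adjusted p = 0.0659) or knockout saline replicate 2 (0.0553) or 3 (0.0754), Btg2 without knockout saline replicate 2 (0.0535) or 3 (0.0506), and Il1b without knockout saline replicate 3 (0.0506). S100a8 lost its call without wild type saline replicate 3 (0.0613) or knockout saline replicate 1 (0.0818) or 3 (0.0812), and Csf3r without the same arrays (0.0521, 0.0576 and 0.0747). Of the immediate early genes, 1 or 2 passed without wild type saline replicate 2 or 3, and 3, 0 or 0 without knockout saline replicate 1, 2 or 3. Of 23 collagen chains 1 was lower (5 adjusted over the list alone), Col3a1 at -0.55, and camera gave adjusted p = 0.000669, and adjusted p = 0.745 with an estimated correlation. Col3a1 lost its call without wild type saline replicate 1 (0.0983), 2 (0.0802) or 3 (0.0899) or knockout saline replicate 1 (0.0893), 2 (0.0885) or 3 (0.137), as the mean of all its probe sets (0.0768) and with the replicate number as a block (0.0724). Of 17 collagen processing genes 1 was lower (5 adjusted over the list alone), Serpinh1 at -0.55, lost without knockout saline replicate 1 (0.0604) or 3 (0.0531), and the list had adjusted p = 0.000131, and adjusted p = 0.494 with an estimated correlation. Of 27 cell cycle genes 0 passed (0 adjusted over the list alone), with a median of -0.20, at adjusted p = 0.000951, and adjusted p = 0.745 with an estimated correlation, a call lost without wild type saline replicate 2 (0.27). Mesothelial markers had a median of -0.473 with 0 of 10 passing (4 lower adjusted over the list alone). Camera gave them adjusted p = 0.000191, 0.494 with an estimated correlation and 0.067 with array weights. Macrophage and monocyte markers had a median of 0.11 with 1 of 27 higher (5 adjusted over the list alone). Their camera adjusted p was 0.000269, and 0.548 with an estimated correlation. Adipocyte genes, markers of fat near the lung, had a median of 0.91 with 0 of 10 passing (0 adjusted over the list alone), at adjusted p = 0.000963, and adjusted p = 0.548 with an estimated correlation; without wild type saline replicate 2 the median was 0.23 and the call was lost (adjusted p = 0.0637). Camera called 16 lists, 10 up and 6 down, and 1 with an estimated correlation, that of the immediate early genes, and fry called 4.

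The genotypes were compared after injury on the 3 knockout against the 3 wild type bleomycin arrays. Saa3 was 16.4-fold lower in knockout lungs (log2 difference -4.04 ± 0.50, SE, n = 3 per group, adjusted p = 0.000236), Chl1 at least 13.3-fold lower (-3.74 ± 0.23, adjusted p = 3.67e-06), Arg1 11.6-fold lower (-3.54 ± 0.43, adjusted p = 0.000236), Timp1 8.51-fold lower (-3.09 ± 0.31, adjusted p = 5.59e-05) and Fst 6.78-fold lower. Retnla was 6.35-fold lower (-2.67 ± 0.22, adjusted p = 2.13e-05). Higher in knockout lungs were Acoxl (5.5-fold), Nrn1 (5.20-fold), the xenobiotic-metabolizing enzyme Cyp1a1 (4.76-fold), Mid1 (4.76-fold, on its brightest probe set only) and Slc7a10 (4.63-fold). In total 2804 genes passed, 1369 higher and 1435 lower, 394 of them at least 2-fold. The count was 1863 without wild type bleomycin replicate 1 and 1653 without knockout bleomycin replicate 1.

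Collagen, contractile and cell cycle lists were lower, and B and plasma cell, NK, ciliated cell and alveolar type 2 lists higher, in knockout than in wild type bleomycin lungs. All 27 cell cycle genes were lower (27 adjusted over the list alone), with Plk1 at -1.59 ± 0.13. For the cell cycle genes, camera gave adjusted p = 2.37e-31, and adjusted p = 0.158 with an estimated correlation. Of 23 collagen chains, 17 were lower and 0 higher (20 and 0 adjusted over the list alone), with Col1a1 3.20-fold lower (-1.68 ± 0.19, adjusted p = 0.000145). For the collagen chains, camera gave adjusted p = 3.43e-15, and adjusted p = 0.158 with an estimated correlation. Of 14 contractile genes, 9 were lower (10 adjusted over the list alone), with Acta2, the smooth muscle actin of myofibroblasts, at -0.91 ± 0.19 (adjusted p = 0.00585) and Tagln at -0.92. For the contractile genes, camera gave adjusted p = 8.23e-07, and adjusted p = 0.234 with an estimated correlation. Of 24 TGF-beta and growth factor genes, 13 were lower (17 adjusted over the list alone), with Igf1 3.54-fold lower. For the TGF-beta and growth factor genes, camera gave adjusted p = 2.11e-08, and adjusted p = 0.0617 with an estimated correlation. Of 17 B and plasma cell markers, 13 were higher (17 adjusted over the list alone), with Jchain 3.74-fold and Igha 2.55-fold higher. For the B and plasma cell markers, camera gave adjusted p = 1.72e-10, and adjusted p = 0.158 with an estimated correlation. Of 14 NK and cytotoxic markers, 11 were higher and 1 lower (12 and 1 adjusted over the list alone), with Gzma 3.57-fold higher. For the NK and cytotoxic markers, camera gave adjusted p = 1.31e-07, and adjusted p = 0.158 with an estimated correlation. Of 19 ciliated cell markers, 14 were higher (16 higher and 1 lower adjusted over the list alone), with Tppp3 2.29-fold higher. For the ciliated cell markers, camera gave adjusted p = 1.8e-08, and adjusted p = 0.204 with an estimated correlation. Of 17 alveolar type 2 markers, 9 were higher (11 adjusted over the list alone), with the surfactant lipid transporter Abca3 1.67-fold higher. For the alveolar type 2 markers, camera gave adjusted p = 2.8e-05, and adjusted p = 0.418 with an estimated correlation. Of 18 injury-associated and basal keratin genes, 7 were lower and 0 higher (9 and 0 adjusted over the list alone), with Cldn4 at -1.29, and camera gave adjusted p = 9.26e-06, and adjusted p = 0.199 with an estimated correlation. T cell markers (5 higher and 1 lower of 18, 5 and 2 adjusted over the list alone) and alveolar type 1 markers (2 higher and 1 lower of 17, 2 and 1 adjusted over the list alone) were not called as lists (adjusted p = 0.0787 and 0.0682). Of 12 cardiac muscle genes 0 passed (0 adjusted over the list alone), with a median of 0.78, at adjusted p = 0.00265, and adjusted p = 0.488 with an estimated correlation, a call lost without knockout bleomycin replicate 3 (0.121). The control probe set for the 5 prime end of 18S ribosomal RNA had a mean of 10.72 ± 1.03 (SD, n = 3) on knockout and 7.85 ± 2.06 on wild type bleomycin arrays, a difference of 2.87 (adjusted p = 0.185). Camera called 23 lists, 8 up and 15 down, not all of them described here, and 0 with an estimated correlation, and fry called 26.

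Genes that differed between genotypes with and without injury were sought in the average over treatments and in both comparisons. On average, Mid1 was 5.98-fold (on its brightest probe set only), Lrmda 3.03-fold, Nrn1 2.60-fold, the orphan receptor gene Nr4a1 2.53-fold and S100a9 2.5-fold higher in knockout lungs, and Timp1 (log2 difference -1.75 ± 0.22), Wdfy1 (-1.58 ± 0.10), Dubr (-1.55 ± 0.07), Plcxd2 (-1.55 ± 0.12) and Retnla (-1.51 ± 0.16) were lower. Of these genes, Nrn1, Timp1 and Retnla passed after bleomycin but not after saline, so their averages do not show a difference without injury. Retnla had -2.67 after bleomycin and -0.34 after saline (adjusted p = 0.648). In total 1631 genes passed, 734 higher and 897 lower, 79 of them at least 2-fold. For genotype averaged over treatments, 616 passed without wild type saline replicates 2 and 3. Both after saline and after bleomycin, 17 genes were higher and 26 lower in knockout lungs, where independent calls would share 4.06 and 2.76; 6 genes went opposite ways. Across all genes, which are not independent replicates, the 2 genotype differences correlated with r = 0.168.

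Part of the genotype differences lay around Retnlb. By the order of genes in a mouse reference annotation (GRCm38.p6; the files name no build), 23 of 1628 placed genes called on average (1.41%) lay within 10 Mb of Retnlb, against 86 of 18032 tested genes (0.477%; odds ratio 3.72, Fisher's exact test, two-sided, p = 1.45e-06). The near genes numbered 15 without wild type saline replicate 1 and 14 without knockout bleomycin replicate 1. Dubr, Slc35a5, Plcxd2 and Nxpe3 are among them, at log2 differences of -1.80, -1.49, -1.42 and 1.04 after saline and of -1.30, -1.46, -1.68 and 1.47 after bleomycin; Nxpe3 was chosen after its values were seen. Retnla, directly beside Retnlb in the order of measured genes, differed after bleomycin but did not pass after saline (-0.34, adjusted p = 0.648). Over the whole chromosome the odds ratio was 1.21 (Fisher's exact p = 0.166). The window does not mark where such differences end. Outside it on this chromosome, Timmdc1 (0.99 after saline, 1.03 after bleomycin) and B4galt4 (-0.85 and -0.60) were called in both treatments. These genes were chosen after their values were seen. Pla1a and Stfa2l1 also lie on this chromosome outside the window.

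**Figure D4:**
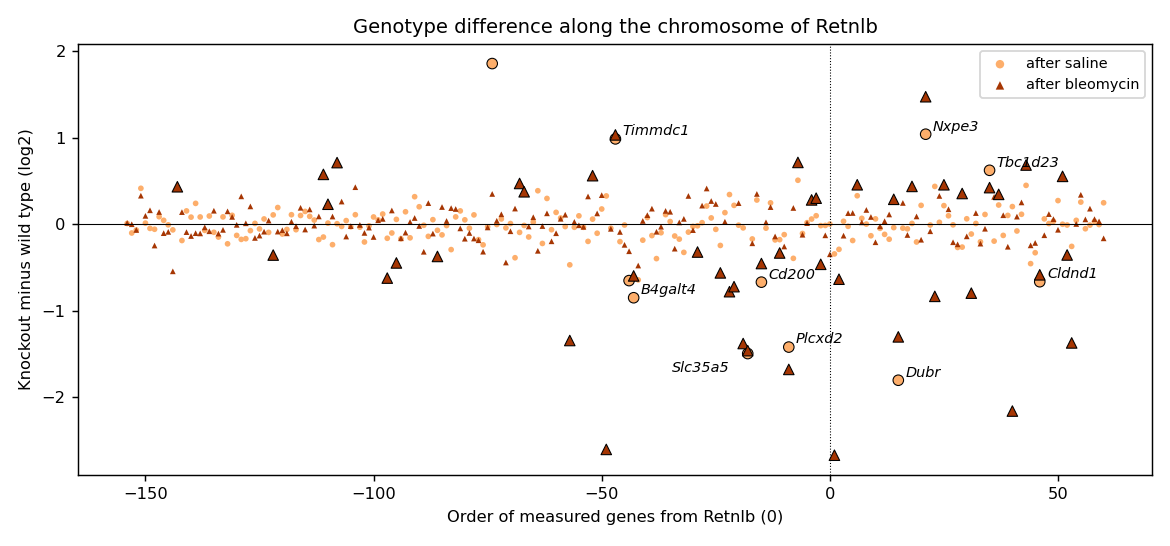
Log2 difference between knockout and wild type lungs, after saline and after bleomycin, of the tested genes around Retnlb in their order along the chromosome, with labels on genes called in both treatments. Larger symbols with an edge passed the test; Dubr lies at -1.80 after saline and -1.30 after bleomycin, and Nxpe3 at 1.04 and 1.47.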

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

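Of the tests in this part, the odds ratios for genes called in both treatments and after saline alone were chosen after the result was seen, as were leaving out each array for the genes near Retnlb, the count of splits without the one that exchanges labels and the list tests of a scale factor. The results listed are those of genes named by size of change, of the resistin family and of gene lists for which the test of the difference between the 2 bleomycin responses passed, and the called probe sets without a gene. Values are log2 changes in knockout minus those in wild type. Those of Chl1, Stfa2l1 and Fabp1 rest in part on group means near background (3.64 for Chl1 and 4.27 for Stfa2l1 in wild type saline lungs, 3.96 for Fabp1 in wild type bleomycin lungs).

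Genes that rose in wild type lungs and whose response was lower in knockout lungs were Saa3 (-3.943), Chl1 (-3.884), Arg1 (-4.152), Tnc (-2.047), Timp1 (-2.689), Thbs4 (-2.647), Fst (-2.945), Pla1a (-2.928), Clec4n (-1.387) and Retnla (-2.325). Genes that fell in wild type lungs and had a higher response in knockout lungs were Fabp1 (2.445), Bex2 (1.89), Slc7a10 (2.264), Nrn1 (2.002) and Acoxl (2.527). Ccl8 (-1.917) lost its call without wild type saline replicate 3 (adjusted p = 0.0518), wild type bleomycin replicate 1 (0.0501) or knockout saline replicate 1 (0.0692) or 2 (0.0587).

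The calls of 4 other genes hung on more arrays. Of these, Stfa2l1 (log2 difference 1.86) and Egr1 were higher in knockout than in wild type saline lungs, which is part of their difference between responses. Stfa2l1 (-1.506) lost its call without wild type saline replicate 1 (adjusted p = 0.0744), 2 (0.0639) or 3 (0.0765), wild type bleomycin replicate 1 (0.0782) or 2 (0.0514), knockout saline replicate 1 (0.105) or 3 (0.0906), or knockout bleomycin replicate 1 (0.0797) or 2 (0.085), with trend and robust eBayes (0.0566) and as the mean of all probe sets (0.051). Cyp1a1 (2.273) lost it without wild type saline replicate 1 (0.0739) or 2 (0.0648), knockout saline replicate 1 (0.0795), 2 (0.0642) or 3 (0.0632), or knockout bleomycin replicate 1 (0.0842) or 2 (0.0536), with trend and robust eBayes (0.0801) and with the replicate number as a block (0.0539). Egr1 (-1.739) lost it without wild type saline replicate 2 (0.0573) or 3 (0.0535), wild type bleomycin replicate 1 (0.055), knockout saline replicate 2 (0.0604) or 3 (0.0659), or knockout bleomycin replicate 1 (0.076), with trend and robust eBayes (0.0566) and with array weights (0.0994). Fos (-1.713) lost it without wild type saline replicate 2 (0.0827) or 3 (0.077), wild type bleomycin replicate 1 (0.0849) or 3 (0.068), knockout saline replicate 1 (0.0898), 2 (0.0932) or 3 (0.0586), or knockout bleomycin replicate 1 (0.0983) or 2 (0.0845), with trend and robust eBayes (0.0843), as the mean of all probe sets (0.0505) and with array weights (0.164).

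Lists with a lower response in knockout lungs had median differences of -1.181 for cell cycle genes, -0.777 for matrix glycoproteins, -0.575 for matrix proteases, -0.525 for collagen chains, -0.438 for TGF-beta and growth factor genes, -0.558 for contractile genes, -0.545 for macrophage markers, -0.36 for type 2 and alternative macrophage activation genes, -0.477 for chemokines, -0.436 for complement genes, -0.334 for injury-associated keratin genes, -0.331 for lymphatic markers, -0.464 for immediate early genes and -0.348 for the resistin family. Lists with a higher response had 0.672 for club cell, 0.578 for ciliated cell, 0.578 for NK and cytotoxic, 0.527 for B and plasma cell, 0.484 for alveolar type 2 and 0.225 for vascular endothelial markers. None of these lists was called with an estimated correlation, the smallest being adjusted p = 0.0539 with an estimated correlation for TGF-beta and growth factor genes. The immediate early list was already higher in knockout than in wild type saline lungs (median 0.735). With bleomycin its median change was 0.084 in wild type and -0.242 in knockout lungs.

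Collagen processing genes (-0.141) lost their list call without wild type saline replicate 1 (adjusted p = 0.0615), wild type bleomycin replicate 1 (0.162), knockout saline replicate 2 (0.052) or 3 (0.139), or knockout bleomycin replicate 1 (0.0651) or 2 (0.107). Alveolar type 1 markers (0.202) lost theirs without wild type saline replicate 1 (0.0561) or 3 (0.095), wild type bleomycin replicate 1 (0.477), knockout saline replicate 1 (0.0901) or 2 (0.0911), or knockout bleomycin replicate 1 (0.0964) or 2 (0.0551). The p53 list (-0.173) lost its call without wild type saline replicate 3 (0.0752) or knockout bleomycin replicate 1 (0.0575). The filter on dim genes ended the list calls of collagen processing genes (0.492), p53 genes (0.0751) and the resistin family (0.0654). Array weights ended those of collagen processing genes (0.0927) and alveolar type 1 markers (0.196), and the mean of all probe sets that of alveolar type 1 markers (0.174). Of 9211 probe sets without a gene in the annotation, 682 were called for bleomycin in wild type lungs.

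The knockout response was smaller, at a ratio of 0.449. A knockout array that did not respond is argued against, since the ratio reached at most 0.512 when any 1 knockout bleomycin array was left out. A factor common to every gene, as a weaker injury or a lower delivered dose may give, stays open. With factors of 0.45 or 0.5, the fewest departing genes were 2, against 914 at a factor of 1 (Igha, 1.69 above the scaled response, and Rgs2, -0.81, chosen after their values were seen). So few departures do not show 1 factor, since these factors were picked for the fewest. In simulated data, 18% and 66% of response differences of 0.5 and 1 on the log2 scale were called, so departures may be missed. That simulation tested a factor of 1, so the share of departures missed at 0.45 or 0.5 was not measured. Of 42 lists, camera called 17 as departing from 0.45, among them contractile genes (-0.594, adjusted p = 4.21e-11), whereas with an estimated correlation and with fry 0 were called. An effect of Retnlb on the injury or its repair is the biological explanation that the design names; it may give the same values and was not told apart from a weaker injury, for which no measure is held. A difference of background between the genotypes was not told apart either. Nnt and Wdfy1, on other chromosomes than Retnlb, had log2 differences between genotypes of -1.59 and -1.73 after saline. After bleomycin these were -1.1 and -1.43.

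Genes that differ between genotypes lay near Retnlb. Sequence linked to the targeted allele may account for this and was not told apart from an effect on neighbouring genes. Of 43 genes called with the same sign in both treatments, 7 lay within 10 Mb (Fisher's exact p = 1.23e-09, odds ratio 44.0). These are part of the same calls, and either explanation would place them there, so this count does not decide between them. For the genes called after saline, the smaller bleomycin response is argued against, since they were enriched without bleomycin (odds ratio 19.3), whereas it stays open for the rest, as 30.4% (7 of 23) of the near genes called on average were called after saline. Sequence differences under single probe sets also stay open, since 68.2% (15 of 22) of further probe sets of these genes moved the same way at an unadjusted p under 0.05. These probe sets are not independent, as several are of Nectin3, and Dubr and Nxpe3 had none in this count. On average over treatments, those of Slc35a5 (-1.15) and Plcxd2 (-0.65) moved the same way, and that of Senp7 (0.29) the opposite way. An effect of Retnlb on its neighbours, the biological explanation, was not tested.

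In knockout saline lungs 6 of 17 immediate early and 5 of 13 neutrophil genes were higher, the neutrophil list with adjusted p = 0.219 with an estimated correlation. A single array as the whole cause is argued against for the immediate early list, whose median of 0.735 stayed at 0.674 or more without 1 knockout saline array and at 0.580 or more without 1 wild type saline array. More blood in the knockout lungs may account for the neutrophil genes and cannot be told apart: Hba-a1, near the floor, and Alas2, which spread from 6.356 to 8.256 over the arrays, had an upper 95% limit of 0.954 for their mean change, above 0.3005, which is 0.5 of the neutrophil median, while platelet genes had a list median of 0.406 with 0 of 9 passing. Handling or time of collection, on which immediate early and circadian clock genes depend (clock list median -0.164), and an effect of the genotype stay open.

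Other splits of the samples gave these counts. For bleomycin in wild type the real split gave 5045 genes and the highest of the others 0; for bleomycin in knockout 594 and 0, for knockout against wild type after saline 89 and 1, and after bleomycin 2804 and 0; in each, 1 of 10 splits gave as many, and 10 are too few for a share under 0.05. A chance division of these arrays is argued against for bleomycin averaged over genotypes (4934, highest other 3022) and for genotype averaged over treatments (1631, highest other 1218). In each, 1 of 100 splits, the real one, gave as many. Since separate animals are not stated, this count says nothing about chance between animals. For the difference between responses, 5 of 100 splits gave at least 914, so by that count chance is not excluded. The count cannot decide the question, since splits that leave most arrays in their groups can keep a real difference. Those with 952 and 915 genes moved 2 arrays into another group, and that with 953 moved 8. Some other splits that moved 2 arrays gave 0 genes. The highest other, 1631, is a split that exchanges the genotype labels within a treatment and so tests the genotype average, not the absence of a difference. Without it 4 of 99 splits gave as many, the highest other being 953, and this later count is not used to exclude chance.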

How the results depend on the processing

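Leaving out the 2 arrays farthest from their groups and leaving out each array for the locus were chosen after seeing the data. Signal near background limits Retnlb, whose sign turned after saline and in the knockout response. Among alternatives other than leaving out an array, 3710 of 3849 results for named genes kept sign and side of the threshold, 131 lost the call, 6 gained one and 2 turned; for lists 516 of 535 kept both and 19 lost the call. With 1 array left out these were 3478 of 4074 (581 lost, 4 gained, 11 turned) and 743 of 780 (37 lost). The cause of the values below was not tested unless fewer genes or arrays give it.

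A 2-fold minimum left 738 genes (bleomycin in wild type), 90 (in knockout), 307 (difference of the bleomycin response between genotypes, below the difference), 24 (knockout against wild type after saline), 394 (after bleomycin), 343 (bleomycin average) and 79 (genotype averaged over treatments). With only its 2 groups in the fit, genotype after saline gave 37. Array weights gave 1286 (bleomycin in knockout), 1888 (difference) and 1105 (genotype after saline). The replicate number as a block gave 601 for the difference. Same-numbered arrays deviated from their groups with a mean r of -0.037 (-0.297 to 0.203 over 18 pairs), which gives no sign of pairing. Whether the numbers mark a shared batch is not stated in the labels and was not settled by these values. With an estimated correlation, camera called 0, 0, 0, 1 and 0 lists (bleomycin in wild type, in knockout, difference, genotype after saline, after bleomycin), and fry called 12 in knockout, 14 for the difference and 4 after saline. Over the whole chromosome the odds ratio was 1.208. Without wild type saline replicates 2 and 3, which leaves 1 such array assumed to vary like the others, the counts were 2805 (bleomycin in wild type), 151 (difference), 35 (genotype after saline) and 616 (genotype average).

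With each array left out, counts ranged from 4052 to 4671 for bleomycin in wild type, 211 to 672 in knockout, 380 to 1052 for the difference, 24 to 58 for genotype after saline, 1653 to 2617 after bleomycin, 4170 to 5019 for the bleomycin average and 1112 to 1654 for the genotype average. The ratio of responses ranged from 0.409 to 0.512 and the locus odds ratio from 2.72 to 3.91. Retnlb after saline turned to -0.037 with array medians subtracted and ranged from -0.069 to 0.078 with an array left out, and its response in knockout from -0.134 to 0.011. Retn: difference of the bleomycin response between genotypes turned to 0.282 with array weights and ranged from -0.857 to 0.289, and its genotype difference after bleomycin from -0.318 to 0.828. Retnla in knockout ranged from -0.581 to 0.012.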

Other observations

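The tests of the control probe sets in this part were chosen after the result was seen. Further lists for bleomycin in wild type lungs, with limma's camera, were as follows. Of 19 p53 response and senescence genes, 11 rose and 1 fell (11 and 2 adjusted over the list alone), with the cell cycle inhibitor Cdkn1a up by a log2 change of 1.93 ± 0.18 (n = 3 per group) and Eda2r by 1.76, at adjusted p = 3.76e-05, and adjusted p = 0.154 with an estimated correlation. Of 17 circadian clock genes, 10 fell and 3 rose (11 and 4 adjusted over the list alone), with the repressor Nr1d1 at -1.21, at adjusted p = 0.0168, and adjusted p = 0.178 with an estimated correlation. Of 8 lymphatic endothelial markers, 4 rose and 1 fell (5 and 1 adjusted over the list alone), with Mmrn1 at 1.18 and Lyve1 at -0.49, at adjusted p = 0.0216, and adjusted p = 0.232 with an estimated correlation; the call was lost without wild type saline replicate 2 (0.0532) and with array weights (0.089). Of 25 interferon-stimulated genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone), at adjusted p = 0.0344, and adjusted p = 0.65 with an estimated correlation, a call lost without wild type saline replicate 3 (0.0762) or wild type bleomycin replicate 3 (0.185), with the filter on dim genes (0.127) and as the mean of all probe sets (0.0564). Of 17 immediate early genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with Egr2 at 1.63 and Jun at -0.60, at adjusted p = 0.0455, and adjusted p = 0.449 with an estimated correlation, a call lost without wild type saline replicate 2 (0.242) or wild type bleomycin replicate 1 (0.121) or 3 (0.0522), with array weights (median 0.012, adjusted p = 0.575) and with the filter on dim genes (0.0987).

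The following lists were not called in the same comparison. Of 25 fibroblast and pericyte markers, 8 rose and 10 fell (8 and 10 adjusted over the list alone), with the pericyte gene Rgs5 at 2.52 and Inmt at -1.36 (adjusted p = 0.953). Of 18 dendritic cell and MHC class II genes, 7 rose and 3 fell (8 and 4 adjusted over the list alone; adjusted p = 0.0644), of 13 neutrophil markers 2 rose and 4 fell (2 and 5; adjusted p = 0.611), and of 16 eosinophil, basophil and mast cell markers 2 fell (1; adjusted p = 0.305). Of 17 mucin and goblet cell genes, 1 rose and 6 fell (1 and 6; adjusted p = 0.508), and of 10 mesothelial markers 1 rose and 2 fell (1 and 2; adjusted p = 0.702). Of 15 oxidative stress genes, 5 rose and 3 fell (6 and 3; adjusted p = 0.212), with metallothionein Mt2 at 2.56 and Gsta3 at -1.70. Of 18 lipid and cholesterol synthesis genes, 2 rose and 3 fell (2 and 4; adjusted p = 0.357), and of 19 unfolded protein response genes 3 rose and 3 fell (3 and 3; adjusted p = 0.508). Of 9 platelet genes, 6 fell (6 fell and 1 rose; adjusted p = 0.0511), and of 10 thymocyte genes 3 fell (4; adjusted p = 0.0963). Of 12 skeletal muscle genes 1 rose and 1 fell (1 and 1; adjusted p = 0.81), and of 10 adipocyte genes 1 rose and 1 fell (1 and 1; adjusted p = 0.504). None of 5 erythroid (0; adjusted p = 0.888) or 4 sex-linked genes (0; adjusted p = 0.867) passed, and of the 3 measured resistin family genes Retnla rose (2 adjusted over the list alone; adjusted p = 0.18).

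The control probe set for the 5 prime end of 18S ribosomal RNA ranged from 6.56 to 11.5 on the log2 scale over the arrays, with means of 9.46 ± 1.63 (SD, n = 3) in wild type saline, 7.85 ± 2.06 in wild type bleomycin, 8.82 ± 1.42 in knockout saline and 10.72 ± 1.03 in knockout bleomycin lungs. In limma's test over probe sets without a gene, the difference between genotypes after bleomycin was 2.87 (adjusted p = 0.185) and that between responses 3.51 (adjusted p = 0.331), and the middle and 3 prime probe sets had differences between responses of 3.03 and 3.13. The 3 prime minus 5 prime signal, a sign of RNA breakage, differed between genotypes after bleomycin by 0.10 for actin and 0.10 for Gapdh (exact permutation test, two-sided, p = 0.5 for each, where 0.1 is the smallest possible). Bleomycin against saline in wild type gave -0.41 and -0.39 (exact p = 0.3 and 0.4) and knockout against wild type after saline -0.26 and -0.32 (exact p = 0.4 and 0.5). In knockout lungs bleomycin against saline gave -0.055 and 0.035 (exact p = 0.7 for each). On the first principal component, which held 58.5% of the variance, wild type bleomycin arrays lay between 34.9 and 50.9, knockout bleomycin arrays between -7.33 and 4.01 and saline arrays between -23.1 and -16.5.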
